A study of Mus musculus with 20 samples.

How the data were processed

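Per the labels, total RNA of adipocytes from wild-type and Olfm2 knockout mice was measured on 20 expression arrays, 5 for each genotype in each of the depots labelled sc and g. The number in a sample title was taken as that of the mouse, so that an sc and a g array with the same number count as a pair, which the labels do not state. The labels' protocols state extraction with Qiagen reagents and labelling of 100 ng of total RNA with the GeneChip WT PLUS kit and biotin. Per the submitters' processing notes the authors normalised the array signals by RMA and used limma, so the deposited values are log2 signals per probe. The versions are not given in the sources used here, nor is it stated whether RMA was run on all arrays at once. The array medians and ranges were checked and fit that scale. The design text of the series counts 10 arrays under a name made of g and OLFM2 and 10 under a name made of sc and another gene, PKP2, while every label gives Olfm2 as the modified gene; the labels were used. The array build is not stated, so no coordinates are given, and gene order was taken from a RefSeq table of assembly GRCm38.p6.

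The deposited table holds 28846 probes, of which 6640 control probes were left out. Of the other 22206 probes 19572 carry 1 gene symbol, and 2634 carry none here and were used only as a check. Of 55 genes with several probes the one with the highest mean over all arrays was kept, which left 19505 genes. Each of them matched the RefSeq table by Entrez identifier, and 0 symbols differed. For arrays no counts exist, and their number limits the precision.

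The knockout and depot effects were tested in R 4.3.3 with limma 3.58.1, in a fit with a mean for each of the 4 groups (16 residual degrees of freedom) and no covariate. For the knockout effect over both depots the arrays of each mouse were averaged first, so that 5 mice were compared with 5. There were 6 comparisons: knockout against wild type in sc, in g and over both depots, the difference of these effects between depots, and g against sc in each genotype. All p-values of genes are limma's moderated, two-sided ones with Benjamini-Hochberg adjustment over the genes tested, and called means an adjusted p under 0.05. Rose and fell are used for genes and lists that passed. The SE is the moderated SE of the fit, and SD is given over the samples of a group. Olfm2 was also tested by an exact permutation test.

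Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Of 40 lists written before the data were examined 38 were tested. The red blood cell list had fewer than 4 measured genes, and the sex-linked list, also that short, was set aside beforehand as a check. The comparisons, tests, named-gene rule and most alternatives were also fixed before the data were examined. Another 4 lists (hepatocyte, mast cell, lipid-associated macrophage and branched-chain amino acid breakdown genes) were added after the values were seen, are not in the adjustment over 38 lists and get no p-value as sets. A preset correlation ignores how strongly the genes of a list move together, so camera was repeated with an estimated correlation, and fry was run beside it.

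Genes were named by a rule: Olfm2 in each comparison; of called genes whose groups' arrays do not overlap, the 10 largest rises and the 10 largest falls; for the difference between depots the 5 largest each way without the overlap rule; of each list the 4 members with the smallest p and any called member. Where a list had many such members, a few are printed. Genes with Gm or Rik names and olfactory or vomeronasal receptor genes were passed over: 11, 60 and 48 called genes of the sc, g and combined knockout comparisons, 1 of the difference between depots, and 127 and 27 of the wild-type and knockout depot comparisons. Genes outside the rule are marked as chosen after their values were seen.

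Whether the depots of a mouse resemble each other was checked by correlating the residuals of the sc and g arrays over genes. The correlations were between -0.461 and 0.142 with a median of 0.0111, and 3 of 10 numbers matched their own best, which lends the pairing little support, and the fits had no mouse term. The means per mouse rest on that pairing. The mouse as a replicate block was an alternative, with a consensus correlation of 0.0863.

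The fit was tested on simulated data, with noise drawn independently for each gene and array and 200 of 19505 genes changed. At a fold of 1.5 it recovered 63% of them in sc, 56% in g, 75% over both depots, 32% for the difference between depots and 60% and 62% for the depots in wild-type and knockout mice. At a fold of 2 these shares were 91%, 92%, 98%, 67%, 89% and 90%. Of 160, 156, 191, 100, 154 and 156 calls, 6, 8, 18, 1, 5 and 4 were false. Genes that move together and arrays with transcripts of other tissues were not simulated, so these shares need not hold for the real arrays.

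Alternatives fixed beforehand were the mouse block, only the arrays compared, a further quantile normalisation, median centring, a filter on dim genes (at or above the median of all values on at least 5 arrays, 10508 genes), all transcript probes without collapsing, trend and robust moderation, array weights, a fold of at least 1.5, an adjusted p under 0.1 and leaving out each array or mouse. Chosen after seeing the data were covariates for the hepatocyte mean or for the hepatocyte, lymphocyte and skeletal muscle means of the arrays, a covariate for the macrophage mean in g alone, and leaving out arrays with a hepatocyte or a lymphocyte mean above 7. The counts of called genes and the correlation of knockout effects between depots were compared with 100 splits of the samples, the real one included. Counts of called lists were not.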

Results

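Gene expression arrays measured total RNA from adipocytes of wild-type and Olfm2 knockout mice. Olfm2 encodes olfactomedin 2, a secreted glycoprotein, and the series concerns its loss in fat cells in obesity, the fat cell cycle and the build-up of adipose tissue. Per the labels, the adipocytes were derived from adipose tissue and differentiated in culture, and each sample belongs to a depot labelled sc or g. There were 20 arrays in 4 groups of 5: wild-type sc, knockout sc, wild-type g and knockout g. The sample titles carry numbers, and each number occurs once per depot, as in sc286WT and g286 WT. The numbers were taken as those of 5 wild-type and 5 knockout mice with a sample of both depots each, which the labels do not state. The labels do not state whether the cultures were separate, so the p-values measure the spread between these samples. Array medians lay between 5.78 and 5.92 on the log2 scale. Arrays of the same group correlated with a median r of 0.981 across genes (range 0.953 to 0.992). Arrays of the same mouse from the other depot correlated with 0.967, and the remaining pairs with 0.966. Genes are not independent replicates. The number of arrays limits the precision of every comparison.

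Some arrays carried transcripts of other tissues. The mean of 16 hepatocyte markers, liver genes such as albumin, was above 7 on 8 of the 20 arrays: 9.80 and 7.56 on sc300KO and sc318KO, 7.43 and 8.81 on g286 WT and g308 WT, and 9.62, 10.4, 7.50 and 9.18 on g306 KO, g317 KO, g318 KO and g320 KO. On the other 12 arrays it was between 4.63 and 5.72. The group means were 4.89 ± 0.27 in wild-type sc, 6.59 ± 2.08 in knockout sc, 6.28 ± 1.76 in wild-type g and 8.38 ± 2.05 in knockout g (SD, n = 5). Lymphocyte markers averaged 7.80 on sc286WT, 8.08 on sc317KO and 7.85 on sc320KO. Skeletal muscle markers averaged 9.22 and 7.76 on sc286WT and sc307WT and 7.03 on sc317KO, and 6.57 on the next array, sc320KO.

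Olfm2 itself was lower in knockout than in wild-type adipocytes of both depots, with no overlap between the arrays of the genotypes. In sc it was 4.88 ± 0.42 in wild-type and 3.22 ± 0.38 in knockout samples (log2, SD, n = 5), a difference of -1.66 (SE 0.19; limma adjusted p = 0.000152; exact two-sided permutation p = 0.00794). The wild-type sc values were 4.28, 5.25, 5.02, 5.21 and 4.62 for sc286WT, sc287WT, sc307WT, sc308WT and sc309WT, and the knockout sc values 3.49, 2.98, 3.58, 2.67 and 3.36 for sc300KO, sc306KO, sc317KO, sc318KO and sc320KO. In g it was 4.34 ± 0.23 in wild-type and 3.54 ± 0.15 in knockout samples, a difference of -0.80 (SE 0.19; adjusted p = 0.00784; exact permutation p = 0.00794). The wild-type g values were 4.30, 4.60, 4.08, 4.54 and 4.17 and the knockout g values 3.43, 3.61, 3.36, 3.56 and 3.72, in the same order of mice. The probe was dim: 27.6% of genes were dimmer in wild-type sc samples and 19.2% in wild-type g samples, and the negative control probes of the arrays had medians of 4.45 to 4.84. The means of both knockout groups and of wild-type g samples lay below these medians, so the differences give no exact fold of the transcript. Without the 8 arrays with a hepatocyte mean above 7, which leaves 1 knockout g array assumed to vary like the other groups, the g difference was -0.85 (adjusted p = 0.383), and with the macrophage mean as a covariate -0.82 (adjusted p = 0.454). Over 22 alternatives the g difference was between -0.86 and -0.73 (adjusted p from 0.00219 to 0.454) and over 21 the sc difference between -1.98 and -1.52 (adjusted p from 1.94e-05 to 0.0139). The position of the probe relative to the deleted part of the gene is not stated in the labels. The knockout effect on Olfm2 did not pass the test of a difference between depots (0.86 for g minus sc, adjusted p = 0.187), nor did the depots differ in knockout mice (0.32 for g minus sc, adjusted p = 0.403). In wild-type mice the depot difference of Olfm2 was -0.54 (adjusted p = 0.0506; 0.0373 with the mouse as a replicate block, and 0.00532 to 0.135 over 22 alternatives).

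**Figure D1:**
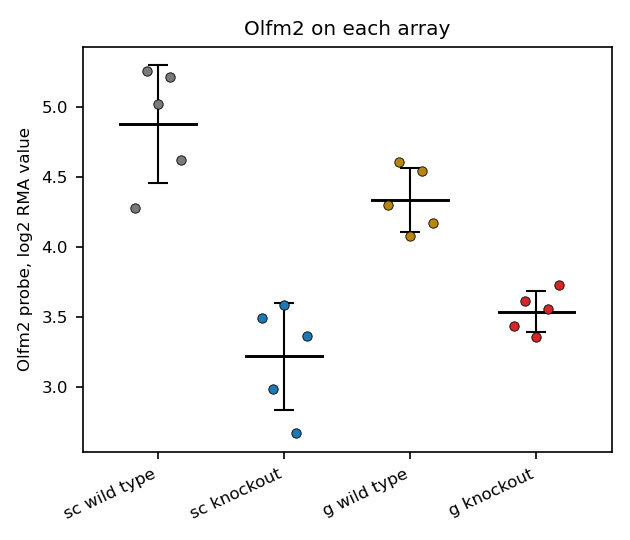
Olfm2 probe value (log2, vertical axis) on each of the 20 arrays by group; points are arrays, the line is the mean and the bars are the SD of 5 arrays. All knockout arrays lie below all wild-type arrays of the same depot, by -1.66 on average in sc and -0.80 in g.

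The comparison of knockout with wild-type sc adipocytes asked which genes change with loss of Olfm2 in this depot. Among the largest rises were Cyp2e1, a cytochrome P450 enzyme (2.44, SE 0.37, adjusted p = 0.0028), Thrsp, a regulator of fatty acid synthesis (1.56, SE 0.20, adjusted p = 0.000724), the acute-phase protein gene Orm3 (1.30, SE 0.17, adjusted p = 0.000756) and the metalloproteinase inhibitor Timp4 (2.29-fold, SE of log2 0.16, adjusted p = 0.000717). Pck1, which makes glycerol precursors for fat storage, rose by 1.09, the WNT inhibitor Apcdd1 by 1.07, the proline oxidase Prodh by 1.03, the amino acid transporter Slc43a1 2.01-fold, the sulfotransferase Chst1 by 0.96 and the medium-chain acyl-CoA synthetase Acsm3 by 1.91. The thermogenic uncoupling protein Ucp1 had the largest fall (-2.56, SE 0.46, adjusted p = 0.00817), followed by the integrin Itgad (-2.11), the G protein subunit Gnal (-2.03), the transferrin receptor Tfr2 (-1.86), Fam122b (-1.75), Olfm2 (-1.66), the growth factor Fgf9 (-1.51, SE 0.17, adjusted p = 0.000152), the copper protein Hephl1 (-1.51), the keratin Krt79 (-1.49, SE 0.17, adjusted p = 0.000152) and the glycosyltransferase Ugt8a (-1.41). In total 132 of 19505 genes passed an adjusted p of 0.05 in limma, 58 higher and 74 lower, and 2017 had an unadjusted p under 0.05. The arrays of the genotypes did not overlap for 114 of the 132, and for 573 of all genes, where chance gives 0.794% of genes. The count was 60 without sc287WT, 71 without sc300KO, 73 without sc308WT, 79 without sc309WT, 82 without sc317KO and 77 without sc320KO. It was 85 (76 of them shared) with the hepatocyte mean as a covariate and 31 (29 shared) with hepatocyte, lymphocyte and skeletal muscle means as covariates. Of the genes named here, Pck1 and Acsm3 lost their call with the hepatocyte covariate, Orm3, Itgad, Chst1, Prodh, Slc43a1 and Fam122b with the 3 covariates, and Ucp1 without the hepatocyte-high arrays (-1.86, adjusted p = 0.107).

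By gene group, cell division genes were lower in knockout sc adipocytes as a set: 0 of 52 mitosis genes were called, 1 lay above 0 and the median was -0.33 (camera adjusted p = 2.66e-12; adjusted p = 0.691 with an estimated correlation). Macrophage markers fell as a set, with 1 of 23 called, the mannose receptor Mrc1 (-0.55, adjusted p = 0.0371), 10 lower when adjusted over the list alone, and a median of -0.43 (camera adjusted p = 6.81e-06; 0.691 as adjusted p with an estimated correlation). Collagens and other matrix genes fell, with 2 of 34 called, the proteoglycan Lum (-1.11, adjusted p = 0.0117) and the matrix protein Postn (-1.17, adjusted p = 0.04), 6 adjusted over the list alone. The median was -0.21 (adjusted p = 1.74e-07; adjusted p = 0.691 with an estimated correlation). Cholesterol synthesis genes had a median of -0.19 (adjusted p = 0.0011; adjusted p = 0.691 with an estimated correlation), with 1 of 20 higher, the squalene synthase Fdft1 (0.56), and 1 lower, the sterol dehydrogenase Nsdhl (-0.83); adjusted over the list alone, 1 was higher and 6 were lower. Fatty acid synthesis genes went both ways: Thrsp and the desaturase Fads1 (0.90) rose, the citrate carrier Slc25a1 (-0.62) and malic enzyme Me1 (-0.46) fell, also when adjusted over the list alone, and the list did not pass (median 0.04, adjusted p = 0.383). Of 30 mature adipocyte markers 2 rose, Pck1 and the transcription factor Klf15 (0.90), with 4 higher and 1 lower adjusted over the list alone. The median was 0.06 (adjusted p = 0.0479; adjusted p = 0.722 with an estimated correlation) and the call was lost without sc286WT (median -0.01) and with the hepatocyte covariate (adjusted p = 0.147). Endothelial markers (median -0.28, adjusted p = 0.000171), core histone genes (-0.20, adjusted p = 0.000204), cytoplasmic ribosomal protein genes (0.12, adjusted p = 0.000116) and skeletal muscle markers (-0.90, adjusted p = 0.042) passed as sets with no member called; with an estimated correlation their adjusted p were 0.691, 0.691, 0.722 and 0.704. The skeletal muscle median was 0.00 without sc286WT, and the histone call ended with the hepatocyte covariate (adjusted p = 0.269). Without the lymphocyte-high arrays 4 calls ended, those of endothelial (median -0.07, adjusted p = 0.823), ribosomal (-0.06, adjusted p = 0.102), mature adipocyte (0.05, adjusted p = 0.102) and cholesterol synthesis genes (-0.04, adjusted p = 0.377). The lowest cholesterol synthesis means in sc were on 2 of these arrays, 7.79 on sc317KO and 7.75 on sc320KO, beside 8.10 to 8.34 on the other knockout sc arrays, 8.06 on sc286WT and 8.24 to 8.28 on the other wild-type ones. Single called members of lists that did not pass were the kinase Sgk1 (-0.80) among glucocorticoid-induced genes, the heme oxygenase Hmox1 (-0.76) and the glutathione transferase Gstm1 (0.64) among NRF2 targets, the serine synthesis enzyme Phgdh (0.62) in the unfolded protein response list and the secreted IGF-binding protein Igfbp4 (0.41) among senescence-associated secreted factors. For the glucocorticoid-induced list the median (0.07) and the mean (-0.13) differed in sign. Hepatocyte markers had a median of 1.66 in this comparison with 0 of 16 called. Of 38 lists 9 passed camera, 2 higher and 7 lower; fry, whose p asks whether the genes of a list move on balance one way without comparing them with other genes, called 0. At an unadjusted p under 0.05, fry had 4 lists and camera with an estimated correlation 0.

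In the g depot Orm3 rose most (2.78, SE 0.17, n = 5 per genotype, adjusted p = 1.86e-08), followed by Cyp2e1 (2.62, SE 0.37), Timp4 (1.88, SE 0.16, adjusted p = 1.35e-06), the Popeye domain gene Popdc2 (1.83), Thrsp (1.80), Pck1 (1.78), the dystrophin-associated Dtna (1.74), Chst1 (1.71), Apcdd1 (1.65, SE 0.14, adjusted p = 2.42e-06) and the resistin-like Retnla (1.56). The largest falls included genes of mast cells, the proteases Mcpt4 (-2.65, SE 0.38, adjusted p = 0.000206), Cpa3 (-2.63, SE 0.31) and Tpsb2 (-2.19, SE 0.25) and the receptor Mrgprb1 (-2.28, SE 0.31). Gnal (-2.58), Ucp1 (-2.33, SE 0.46), the signalling regulator Rgs1 (-2.29), the chemokine Ccl3 (-2.24), the myosin Myh15 (-2.17, SE 0.22, adjusted p = 8.71e-06) and the prostaglandin D synthase Hpgds (-2.14) fell as well. Of 19505 genes, 2200 were called, 977 higher and 1223 lower, with 4702 at an unadjusted p under 0.05; 1517 of the 2200 had no overlap between genotypes, against 2030 of all genes and a chance share of 0.794%. With the hepatocyte mean as a covariate 1089 genes were called, of which 1044 were among the 2200. Without the hepatocyte-high arrays, which leaves 1 knockout and 3 wild-type g arrays, 43 were called, 40 of them shared, and without g307 WT the count was 1425. With the macrophage mean of the arrays as a covariate limma called 4 genes, all among the 2200: Orm3 (2.52), Timp4 (1.45), Apcdd1 (1.08) and the interleukin receptor Il1r1 (-0.82), named after their values were seen, with 1841 at an unadjusted p under 0.05. The macrophage means of the g arrays did not overlap between genotypes (9.56 to 10.1 in wild-type, 8.27 to 9.31 in knockout), so this covariate is confounded with the knockout.

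Cell cycle genes fell in knockout g adipocytes. Of 52 mitosis genes 37 fell and none rose (0 higher and 45 lower adjusted over the list alone), among them the spindle checkpoint kinase Bub1 (-1.44, SE 0.26), the spindle protein Prc1 (-1.41), the mitotic kinases Pbk (-1.50) and Plk1 (-1.07), and cyclin A2, Ccna2 (-1.17). The list mean was 6.34 ± 0.13 in wild-type and 5.57 ± 0.41 in knockout arrays (SD, n = 5). The list median was -0.80 and camera gave an adjusted p of 4.51e-25 (adjusted p = 0.16 with an estimated correlation). Of 44 DNA replication genes 16 fell (26 adjusted over the list alone), such as the sliding clamp Pcna (-0.89), the ribonucleotide reductase subunit Rrm1 (-0.94) and the helicase subunit Mcm3 (-0.82). The median was -0.38 (adjusted p = 8.83e-12; adjusted p = 0.149 with an estimated correlation). Of 34 core histone genes 12 fell, including H3c6 (-0.91) and H3c11 (-0.84), and 1 rose, H4c8 (0.38); adjusted over the list alone, 18 were lower and 1 higher. The median was -0.33 (adjusted p = 2.55e-10; adjusted p = 0.404 with an estimated correlation). Of 30 cyclins, CDKs and CDK inhibitors 7 fell, with Cdk6 (-1.07, SE 0.13, adjusted p = 7.11e-05) and Cdk1 (-1.08) among them, and 2 rose, the CDK inhibitor Cdkn2c (0.80) and the cyclin Ccnd3 (0.37); adjusted over the list alone, 7 were lower and 3 higher. This list had a median of -0.13 (adjusted p = 0.0324; adjusted p = 0.554 with an estimated correlation) and was not called with the hepatocyte covariate (adjusted p = 0.114). With that covariate 19 mitosis and 8 replication genes were called instead of 37 and 16, with medians of -0.64 and -0.35. With the macrophage covariate limma called 0 of either list (medians -0.18 and -0.08). By camera the mitosis list kept its call with it (adjusted p = 0.00284), while the replication (adjusted p = 0.203), histone (adjusted p = 0.216) and cyclin lists (adjusted p = 0.914) did not pass.

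Genes of the fat cell moved the other way. Of 30 mature adipocyte markers 19 rose and none fell (23 and 0 adjusted over the list alone), including the insulin-responsive glucose transporter Slc2a4 (1.23, SE 0.14, adjusted p = 3.97e-05), resistin, Retn (1.38, SE 0.13, adjusted p = 6.26e-06), the transcription factors Pparg (0.48), Cebpa (0.56) and Klf15 (1.13), the hormone-sensitive lipase Lipe (0.59) and adiponectin, Adipoq (0.36). The list mean was 10.56 ± 0.16 in wild-type and 11.08 ± 0.07 in knockout g arrays (SD, n = 5), beside 11.13 ± 0.13 in wild-type sc arrays. The list median was 0.36 (adjusted p = 3.7e-16; adjusted p = 0.149 with an estimated correlation). Of 17 fatty acid synthesis genes 7 rose (11 adjusted over the list alone), among them Thrsp, fatty acid synthase Fasn (0.80), acetyl-CoA carboxylase Acaca (0.80) and the elongase Elovl6 (0.73). The median was 0.43 (adjusted p = 6.31e-06; adjusted p = 0.23 with an estimated correlation). Of 37 oxidative phosphorylation genes 10 rose (20 adjusted over the list alone), such as the complex I subunits Ndufa5 (0.46) and Ndufv1 (0.36) and the complex III subunit Uqcrq (0.40), with all 37 above 0 and a median of 0.20 (adjusted p = 1.87e-09; adjusted p = 0.149 with an estimated correlation). Of 22 fatty acid oxidation genes 5 rose, including the peroxisomal Ehhadh (0.93) and the mitochondrial Eci1 (0.54), with 8 higher and 1 lower adjusted over the list alone. The median was 0.24 (adjusted p = 0.00107; adjusted p = 0.404 with an estimated correlation). Fasn, Acaca, Elovl6 and Uqcrq were not called with the hepatocyte covariate, while the 4 lists kept their call with it. It left 1 of 17 fatty acid synthesis genes called instead of 7, with 4 below 0 instead of 1, 6 oxidative phosphorylation genes instead of 10 and 14 adipocyte markers instead of 19 (medians 0.33, 0.18 and 0.38). With the macrophage covariate the lists for fatty acid synthesis (adjusted p = 0.253) and oxidation (adjusted p = 0.73) were not called. Mature adipocyte markers (median 0.20, camera adjusted p = 6.1e-07) and oxidative phosphorylation genes (0.17, adjusted p = 6.18e-07) kept their call with it. Hepatocyte markers had a median of 2.07 in this comparison, with 0 of 16 called, and liver also expresses genes of these metabolic lists.

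Macrophage markers fell in knockout g adipocytes. Of 23 macrophage markers 19 fell, with the surface receptor Adgre1 (-1.50, SE 0.23, adjusted p = 0.000389), the growth factor receptor Csf1r (-0.72), the complement gene C1qa (-1.07) and the lipid receptor Trem2 (-1.78) among them, and 1 rose, the scavenger receptor Cd163 (1.04). The counts were the same adjusted over the list alone. The list mean was 9.84 ± 0.23 in wild-type and 8.84 ± 0.45 in knockout g arrays and 8.36 ± 0.11 in wild-type sc arrays (SD, n = 5). The median was -1.03 (adjusted p = 1.01e-17; adjusted p = 0.149 with an estimated correlation). Of 26 inflammatory genes 4 fell, the cytokine Tnf (-1.02), the lipocalin Lcn2 (-1.40) and the adhesion molecules Vcam1 (-0.78) and Icam1 (-0.51), and 8 adjusted over the list alone. The median was -0.34 (adjusted p = 0.000146, and adjusted p = 0.23 with an estimated correlation). With the macrophage covariate, which is confounded with the knockout, it was 0.077 and the list was not called (camera adjusted p = 0.511). Of 28 senescence-associated secreted factors 6 fell, such as the metalloproteinase Mmp3 (-1.99), its inhibitor Timp1 (-1.46) and the growth factor Hgf (-0.89), and 2 rose, Igfbp5 (0.68) among them, or 8 and 3 adjusted over the list alone. The median was -0.36 (adjusted p = 0.0261, and adjusted p = 0.404 with an estimated correlation). It was -0.068 with the macrophage covariate, where the list was not called (camera adjusted p = 0.381). Of 34 collagen and matrix genes 12 fell (13 adjusted over the list alone), including Lum (-1.26), Timp1, Col3a1 (-0.71) and Pcolce (-1.05). The median was -0.20 (adjusted p = 2.16e-05; adjusted p = 0.404 with an estimated correlation). Of 21 immediate early genes 3 fell, Egr2 (-1.15), Myc (-0.58) and Junb (-0.66), with 6 lower and 1 higher adjusted over the list alone. The median was -0.26 (adjusted p = 0.00518, and adjusted p = 0.463 with an estimated correlation). Without the hepatocyte-high arrays, which leaves 1 knockout g array, it was -0.008. The same exclusion gave -0.26 for inflammatory, -0.17 for senescence-associated and -0.17 for matrix genes. With the macrophage covariate the matrix and immediate early lists kept their call (camera adjusted p = 0.000873 and 0.0285). Tnf, Vcam1, Icam1 and Myc were not called with the hepatocyte covariate.

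Of 12 heat shock genes 3 rose in knockout g adipocytes, also when adjusted over the list alone, with the small chaperones Hspb1 (0.80) and Hspb8 (0.72) among them. The median was 0.13 (adjusted p = 0.0335, and adjusted p = 0.404 with an estimated correlation). With the macrophage covariate the list was not called (median 0.17, camera adjusted p = 0.195), and without the hepatocyte-high arrays the median was 0.13. Visceral patterning genes passed with a median of 0.21 (adjusted p = 0.0147; adjusted p = 0.404 with an estimated correlation) and 2 of 11 higher, also adjusted over the list alone, the homeobox gene Hoxc8 (0.94) and thrombomodulin, Thbd (0.91). Mesothelial markers (median 0.47, adjusted p = 0.00436) and ribosomal protein genes (-0.15, adjusted p = 0.00107) passed as sets with no member called; with an estimated correlation the adjusted p were 0.596 and 0.782. With the macrophage covariate the ribosomal median was 0.30 (adjusted p = 2.7e-11). The visceral, mesothelial and ribosomal lists were not called with the hepatocyte covariate (adjusted p = 0.14, 0.294 and 0.475), and without the hepatocyte-high arrays the mesothelial median was -0.30 (adjusted p = 0.0147). Among lists that did not pass, NRF2 targets had 5 of 22 members higher, such as the glutathione transferases Gsta3 (1.24) and Gstm1 (0.66), and 5 lower, such as Akr1b8 (-1.25) and Hmox1 (-0.96), or 6 and 6 adjusted over the list alone (median -0.14, adjusted p = 0.446). In the unfolded protein response list Phgdh rose (1.13, SE 0.14) and Atf3 fell (-1.23), with 3 of 25 higher and 4 lower, or 4 and 5 adjusted over the list alone (median -0.02, adjusted p = 0.489). Clock genes had 4 of 17 higher, among them Nr1d1 (0.61) and Hlf (0.65), and 2 lower, among them Arntl (-0.58), or 5 and 2 adjusted over the list alone (median 0.19, adjusted p = 0.155). The hypoxia and glycolysis list had 3 of 30 members higher, also adjusted over the list alone, Bnip3 (0.63), hexokinase Hk2 (0.50) and glycogen synthase Gys1 (0.71), with a median of 0.00 (adjusted p = 0.489). Cholesterol synthesis genes had 2 of 20 higher, Fdft1 (0.85) among them, and 1 lower, Dhcr7 (-0.53), or 2 and 2 adjusted over the list alone (median 0.01, adjusted p = 0.828). Of 38 lists 17 passed camera in g, 7 higher and 10 lower, and 9 with the macrophage covariate, 6 of them among the 17; fry called 13, and none passed with an estimated correlation, where the smallest adjusted p was 0.149 and 7 had an unadjusted p under 0.05.

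**Figure D2:**
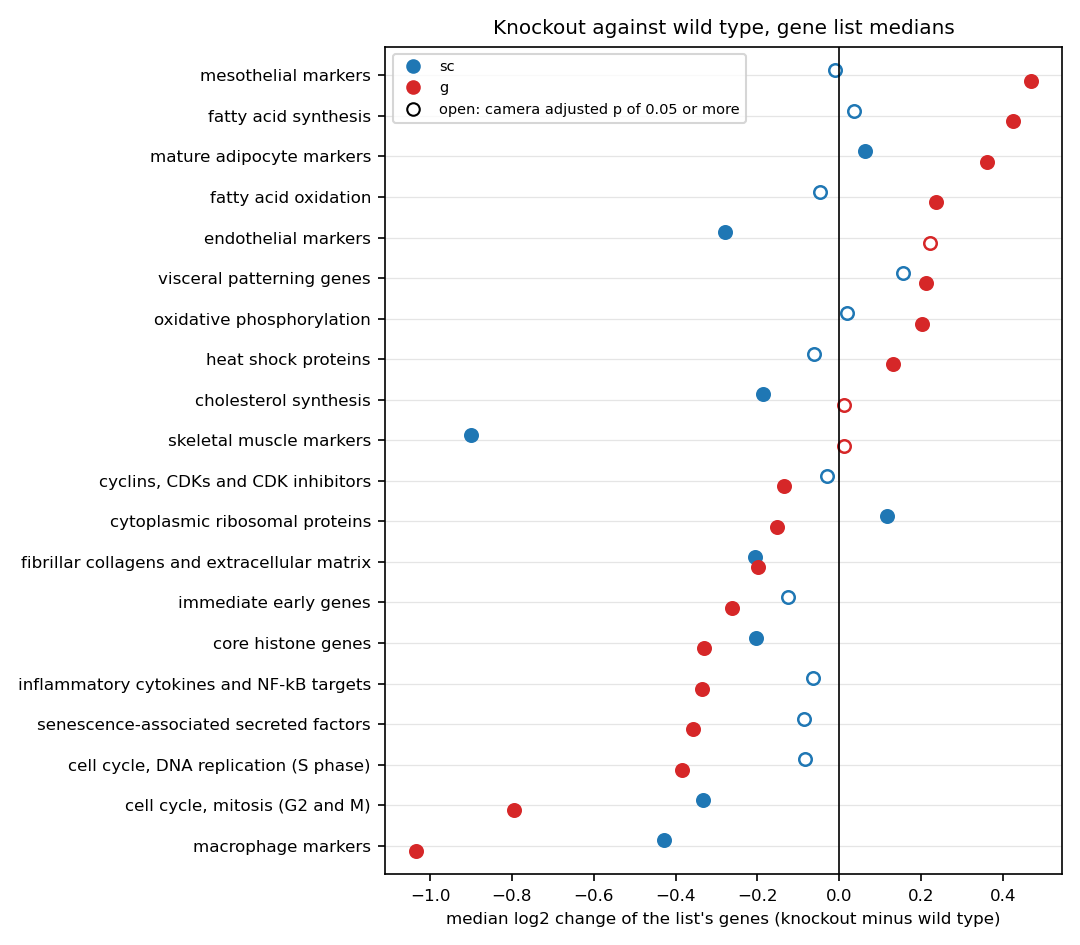
Median log2 change (horizontal axis, knockout minus wild type) of each gene list called in either depot, sc in blue and g in red; open points did not pass camera at an adjusted p of 0.05. Macrophage markers lie at -1.03 in g and -0.43 in sc, mitosis genes at -0.80 and -0.33.

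**Figure D3:**
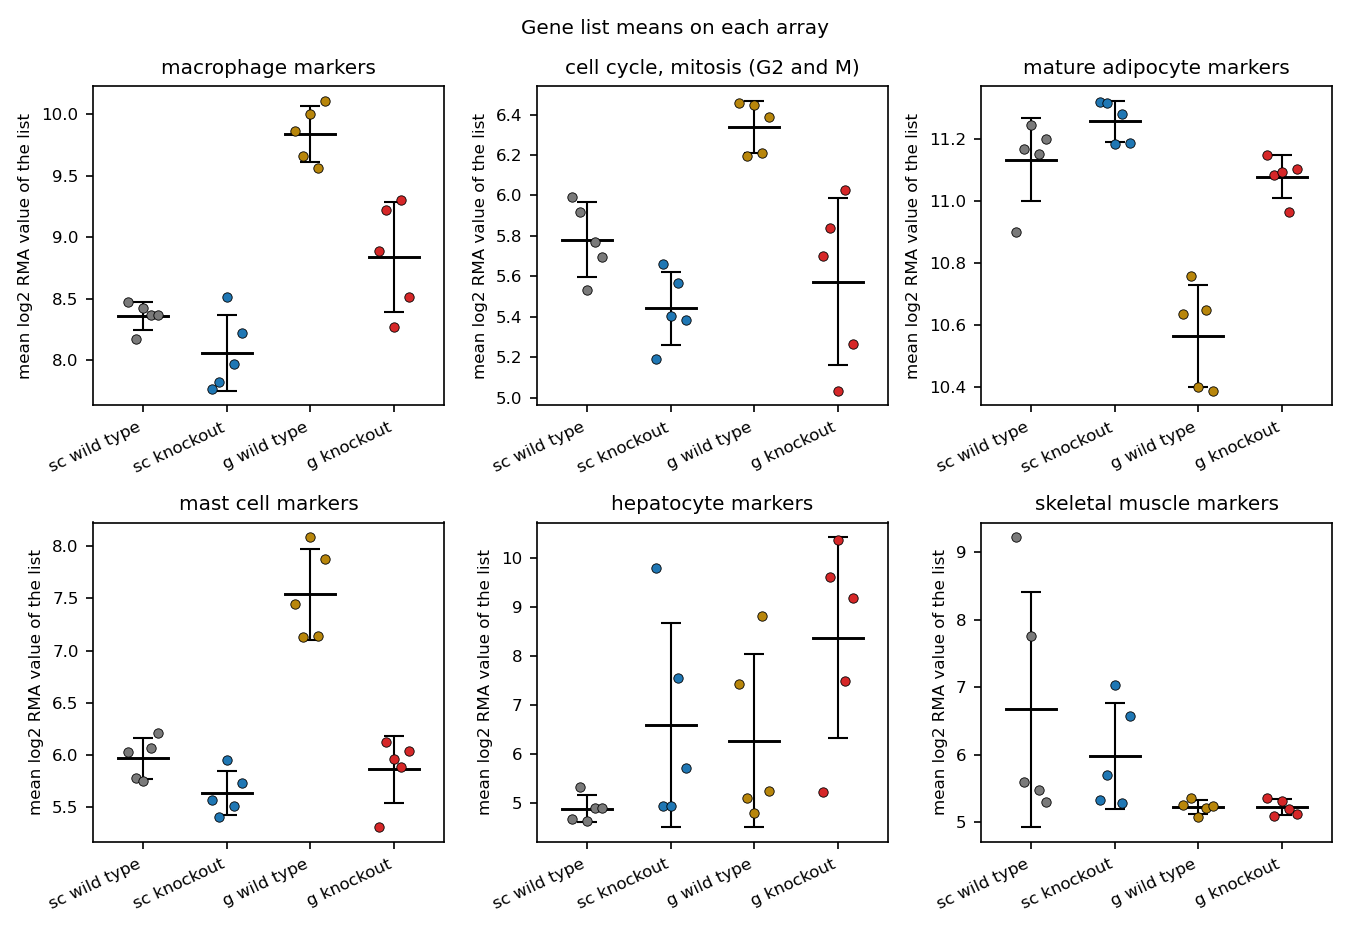
Mean log2 value (vertical axes) of 6 gene lists on each of the 20 arrays by group; points are arrays, the line is the mean and the bars are the SD of 5 arrays. Knockout g arrays lie below wild-type g arrays for macrophage, mitosis and mast cell lists and above them for adipocyte markers, and hepatocyte markers exceed 7 on 8 arrays.

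When the sc and g arrays with the same number, taken as those of a mouse, were averaged, the largest rises were in genes expressed by liver. Cyp2e1 rose by 2.53 (SE 0.27, 5 against 5 mice, adjusted p = 0.000531), albumin, Alb, by 2.25 (SE 0.40, adjusted p = 0.00563), the fibrinogen chain Fgg by 2.23, the urea cycle enzyme Cps1 by 2.10, the major urinary protein Mup3 by 2.19, the serpins Serpina1e, Serpina1c, Serpina1b and Serpina1d by 2.47, 2.37, 2.26 and 2.13 and the sulfotransferase Sult2a8 by 2.12. Ucp1 fell most (-2.45, SE 0.33, adjusted p = 0.00126), and Gnal (-2.30), the proton pump subunit Atp6v0d2 (-2.24), the lipase Lipf (-2.22), Itgad (-2.06), Ubd (-1.87), Rgs1 (-1.76), Mcpt4 (-1.76), S100a8 (-1.69) and Hpgds (-1.67) fell too. Olfm2 fell by 1.23 (adjusted p = 0.000531). All 16 hepatocyte markers, a list added after the values were seen, were called in this comparison (median 1.94), also when adjusted over the list alone. In all, 1612 genes passed, 753 higher and 859 lower, with 3995 at an unadjusted p under 0.05; 1285 of the 1612 did not overlap between genotypes, against 1701 of all genes and a chance share of 0.794%. With the hepatocyte mean of each mouse as a covariate 2 genes were called, Apcdd1 (1.52, adjusted p = 0.0149) and the neuropeptide gene Cck (-1.47, adjusted p = 0.0119), both named after their values were seen; none of the other genes named in this paragraph passed. Alb went from 2.25 (SE 0.40) to 0.03 (SE 0.32, adjusted p = 0.998), while Olfm2 went from -1.23 (SE 0.13) to -1.38 (SE 0.27, adjusted p = 0.319) and Ucp1 from -2.45 (SE 0.33) to -2.78 (SE 0.67, adjusted p = 0.532), so that those calls ended with a larger SE and not a smaller change. The hepatocyte means of the mice did not overlap between genotypes (4.72 to 6.85 in wild-type, 7.28 to 7.66 in knockout mice), so this covariate is confounded with the knockout. The count was 1065 without the mouse of sc307WT and g307 WT, and 1002 without that of sc309WT and g309 WT.

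The 13 gene lists called in this average were all among the 17 called in g. Mitosis genes fell, with 33 of 52 called (45 adjusted over the list alone) and a median of -0.55 (adjusted p = 2.67e-27; adjusted p = 0.335 with an estimated correlation). Macrophage markers fell, with 19 of 23 lower and 1 higher, the same counts adjusted over the list alone. The median was -0.68 (adjusted p = 5.2e-19; adjusted p = 0.247 with an estimated correlation). Mature adipocyte markers rose, with 13 of 30 called (18 adjusted over the list alone) and a median of 0.23 (adjusted p = 1.64e-10; adjusted p = 0.335 with an estimated correlation). Of the 13 lists 5 were higher and 8 lower; fry called 10, and none passed with an estimated correlation, where the smallest adjusted p was 0.247 and 5 had an unadjusted p under 0.05. Across genes the knockout effects in sc and g correlated with r = 0.476 and rho = 0.252, and 57.1% of 19505 genes had the same sign; genes are not independent replicates. Among 100 splits of the mice the median r was 0.0507, and 10 reached the real rho. Of the 132 genes called in sc, 78 were also called in g, all in the same direction, 42 higher and 36 lower. Calls independent between the depots would give 2.91 and 4.64. Both comparisons share 1 estimate of spread per gene, so more overlap than that may arise by chance. The r was 0.0115 without the hepatocyte-high arrays.

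**Figure D4:**
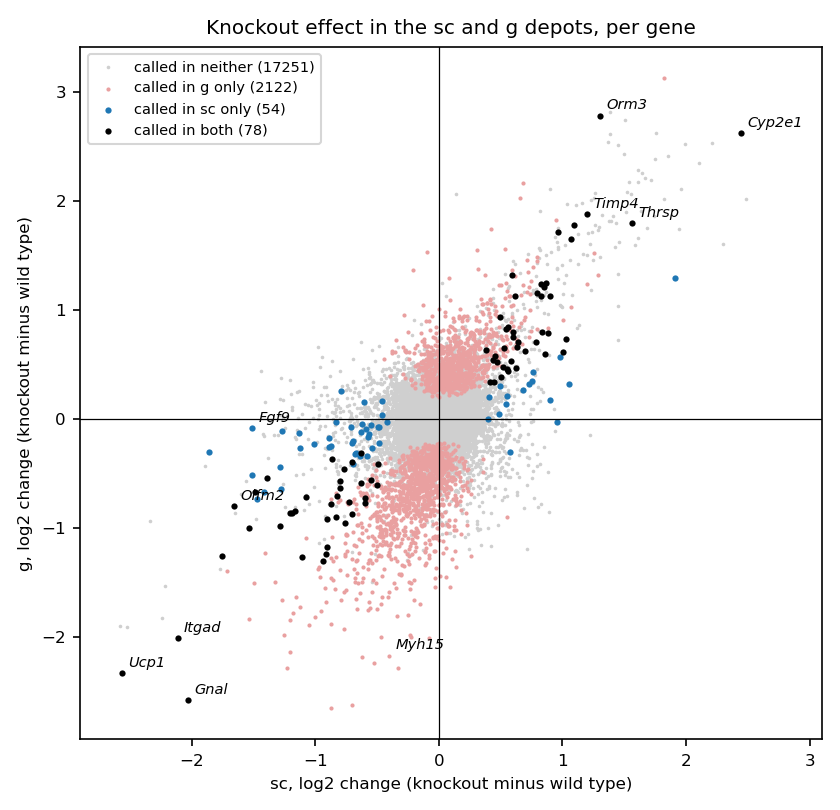
Knockout minus wild type log2 change of each of 19505 genes in sc (horizontal axis) and g (vertical axis); points are genes, coloured by where they were called. The 78 genes called in both depots all lie in the same-sign quadrants, with Cyp2e1 at 2.44 and 2.62 and Ucp1 at -2.56 and -2.33.

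The interaction asked which knockout effects differ between depots. Orm3 rose more in g than in sc (difference 1.48, SE 0.25, adjusted p = 0.0179), the FGF co-receptor Klb rose by 0.96 in g (difference 1.24, SE 0.20, adjusted p = 0.0179), and Disp2 (1.58), the vesicle priming factor Cadps (1.22), the hormone Retn (1.06), the chaperone Hspb8 (1.07) and the lectin Mgl2 (0.81) also had positive differences. For Fgf9 the difference was 1.43 (SE 0.23, adjusted p = 0.0179), since it fell in sc and was at -0.08 in g. Differences were negative for the myosin Myh15 (-1.77, SE 0.30, adjusted p = 0.0223), the cadherin Fat3 (-1.35), the cell adhesion gene Nfasc (-1.15), the receptor Gpr176 (-1.14, SE 0.16, adjusted p = 0.0177), the collagen Col6a5 (-1.02) and the G protein subunit Gna13 (-0.64). In total 15 genes were called, 8 with a positive and 7 with a negative difference, and 2537 had an unadjusted p under 0.05. The count was 32 with the mouse as a replicate block, all 15 among them. It was 41 without sc286WT, 24 without g308 WT and 4 without sc307WT (Orm3, Gpr176, Fat3 and Nfasc). Without the hepatocyte-high arrays 1 gene was called (Col6a5), without the lymphocyte-high arrays 3 (Klb, Gpr176 and a Rik-named gene), and with hepatocyte, lymphocyte and skeletal muscle covariates limma called 0, with 1341 at an unadjusted p under 0.05.

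Between depots, as sets, macrophage markers (median difference -0.61, adjusted p = 1.55e-09) and mitosis genes (-0.48, adjusted p = 3.07e-09) fell more in g than in sc, with 0 members called and 9 and 0 adjusted over the list alone. With an estimated correlation neither list passed (adjusted p = 0.339 and 0.578). Adipocyte markers rose more in g (0.34, adjusted p = 1.36e-12; adjusted p = 0.339 with an estimated correlation), with 1 of 30 called, Retn, and 7 adjusted over the list alone. DNA replication (-0.29, adjusted p = 2.83e-08) and ribosomal protein genes (-0.28, adjusted p = 3.07e-09) had negative median differences, and oxidative phosphorylation (0.20, adjusted p = 8.92e-09), fatty acid synthesis (0.39, adjusted p = 0.000162), fatty acid oxidation (0.22, adjusted p = 3.61e-05) and endothelial lists (0.56, adjusted p = 4.85e-06) positive ones. With an estimated correlation the adjusted p of these 6 lists were 0.339 for replication, oxidative phosphorylation, fatty acid synthesis and fatty acid oxidation genes, 0.578 for endothelial genes and 0.627 for ribosomal protein genes. Of 38 lists 18 passed camera, 10 with a positive and 8 with a negative difference; fry called 2, mature adipocyte markers and oxidative phosphorylation, and camera with an estimated correlation had 4 at an unadjusted p under 0.05.

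Between the depots of wild-type mice, genes that mark the origin of a tissue were among the largest differences. Higher in g were the uroplakins Upk3b (3.67, SE 0.36, adjusted p = 1.58e-06) and Upk1b (2.97), which mark mesothelium, Col6a5 (3.64, SE 0.14, adjusted p = 1.11e-12), Pkhd1l1 (3.05), the WNT inhibitor Sfrp1 (2.94), proenkephalin, Penk (2.88, SE 0.16), Cpa3 (2.80), Ccl3 (2.71), the retinol dehydrogenase Dhrs9 (2.68) and the ubiquitin ligase Rnf128 (2.67). Lower in g were the developmental transcription factors Tbx15 (-2.93, SE 0.30, adjusted p = 1.63e-06), Shox2 (-2.77, SE 0.19), Hoxc10 (-2.54, SE 0.18) and Hoxa10 (-1.94), the muscle genes Casq1 (-2.32), Myl1 (-2.14) and Smpx (-1.81), and Zim1 (-2.09), Rpl39l (-1.96) and H2-M9 (-1.81). Of 19505 genes 3468 were called, 1814 higher and 1654 lower in g, with 5836 at an unadjusted p under 0.05 and 2588 of the called genes without overlap, against 3137 of all genes and a chance share of 0.794%. The mouse as a random replicate block gave 3931 genes. With hepatocyte, lymphocyte and skeletal muscle covariates 1266 genes were called, 1196 of them shared, and Casq1 and Smpx were not among them.

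Of 8 subcutaneous patterning genes 6 were lower in g (7 adjusted over the list alone). The median was -0.57 (adjusted p = 2.09e-06; adjusted p = 0.00907 with an estimated correlation). Visceral patterning genes had 3 of 11 higher, Wt1 (1.73), Tcf21 (1.92) and Osr1 (1.22), and 1 lower, the LIM homeobox gene Lhx8 (-1.23), or 6 and 2 adjusted over the list alone. The median was 0.37 (adjusted p = 0.0117; adjusted p = 0.319 with an estimated correlation). Macrophage markers were higher in g, 19 of 23, with Adgre1 (2.02), Itgam (1.96) and Trem2 (2.43) among them, or 22 higher and 1 lower adjusted over the list alone. The median was 1.52 (adjusted p = 2.13e-23; adjusted p = 0.0412 with an estimated correlation). Mature adipocyte markers were lower in g, 26 of 30 (27 adjusted over the list alone), including Retn (-1.25), Slc2a4 (-0.98) and Adipoq (-0.49). The median was -0.54 (adjusted p = 2.54e-17; adjusted p = 0.0977 with an estimated correlation). Oxidative phosphorylation genes were lower, 31 of 37 (33 adjusted over the list alone), such as Cyc1 (-0.70) and Ndufa8 (-0.62). The median was -0.35 (adjusted p = 2.54e-17; adjusted p = 0.0277 with an estimated correlation). Fatty acid oxidation genes were lower, 15 of 22 (17 adjusted over the list alone), with Acadl (-0.62) and Cpt1b (-0.96). The median was -0.43 (adjusted p = 4.04e-08; adjusted p = 0.124 with an estimated correlation). Of 19 thermogenic genes 6 were lower and 1 higher, or 8 and 1 adjusted over the list alone, with Ucp1 (-1.79), Cidea (-1.33) and Cox8b (-1.18). The median was -0.29 (adjusted p = 0.0171; adjusted p = 0.164 with an estimated correlation). Mitosis genes were higher in g, 26 of 52 (34 adjusted over the list alone), with Bub1 2.64-fold higher. The median was 0.57 (adjusted p = 1.18e-12; adjusted p = 0.319 with an estimated correlation). Of 44 replication genes 14 were higher, Pcna at 0.85, and 2 lower, or 18 and 2 adjusted over the list alone. The median was 0.29 (adjusted p = 2.06e-07; adjusted p = 0.188 with an estimated correlation). Cdk6 was higher by 1.41.

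Among other lists in wild-type mice, mesothelial markers had 11 of 15 higher in g and 1 lower, or 12 and 1 adjusted over the list alone. The median was 1.06 (adjusted p = 6.19e-10; adjusted p = 0.132 with an estimated correlation). NRF2 targets had 10 of 22 higher, also adjusted over the list alone, with the peroxiredoxin Prdx1 at 0.75. The median was 0.42 (adjusted p = 6.34e-05; adjusted p = 0.119 with an estimated correlation). Inflammatory genes had 5 of 26 higher and 1 lower, or 7 and 1 adjusted over the list alone, with Lcn2 at 2.34. The median was 0.47 (adjusted p = 0.00725; adjusted p = 0.319 with an estimated correlation). The metalloproteinase inhibitor Timp1 was higher in g by 1.94. Schwann cell genes had 4 of 10 lower and 1 higher, or 5 and 1 adjusted over the list alone, with Cdh19 (-1.54) and myelin basic protein, Mbp (-1.12). The median was -0.35 (adjusted p = 0.00205; adjusted p = 0.0313 with an estimated correlation). Endothelial markers had 7 of 15 lower (11 adjusted over the list alone), with Erg (-0.89) and Cldn5 (-0.85). The median was -0.47 (adjusted p = 0.000193; adjusted p = 0.463 with an estimated correlation). Smooth muscle and pericyte markers had 4 of 17 lower (5 adjusted over the list alone), with Rgs5 (-1.16). The median was -0.31 (adjusted p = 0.0234; adjusted p = 0.543 with an estimated correlation). Skeletal muscle markers had 1 of 17 lower, Casq1, also adjusted over the list alone. The median was -1.08 (adjusted p = 0.00259; adjusted p = 0.463 with an estimated correlation), and 0.04 with the 3 covariates. Of 38 lists 19 passed camera, 10 higher and 9 lower in g; those for subcutaneous patterning, oxidative phosphorylation, Schwann cells and macrophages also passed with an estimated correlation.

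In knockout mice many of these genes differed between the depots as well. Upk3b (4.34, SE 0.36, adjusted p = 4.98e-07), Upk1b (3.72, SE 0.30), Pkhd1l1 (3.34), Penk (2.65, SE 0.16) and Col6a5 (2.63, SE 0.14, adjusted p = 5.64e-10) were higher in g, and Shox2 (-2.61, SE 0.19), Tbx15 (-2.52, SE 0.30), Hoxc10 (-2.19) and Hoxa10 (-1.87) lower. Also higher in g were the mesothelial genes Gpm6a (2.67) and Nkain4 (2.51), Lcn2 (2.65), the macrophage glycoprotein Gpnmb (2.34) and the small chaperone Hspb7 (2.43). Also lower were the Schwann cell cadherin Cdh19 (-2.33, SE 0.15), Mmp3 (-2.18), the adaptor Grb14 (-1.98), H2-M9 (-1.98), the chemokine Cxcl14 (-1.91) and the steroid dehydrogenase Akr1c18 (-1.85). In total 806 genes were called, 559 higher and 247 lower in g, with 3339 at an unadjusted p under 0.05 and 518 of the called genes without overlap, against 831 of all genes and a chance share of 0.794%. Of the 806, 609 were also called in wild-type mice, 608 of them in the same direction, 445 higher and 163 lower. Calls independent between the genotypes would give 52.0 and 20.9, numbers that the shared estimate of spread per gene may raise. The mouse as a fixed replicate block on the 10 knockout arrays gave 321 genes, 296 of them shared, and those arrays alone without a block 311. Without sc320KO the count was 530, without g306 KO it was 537, and without the hepatocyte-high arrays it was 118.

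Macrophage markers were higher in g in knockout mice too, 14 of 23 (17 adjusted over the list alone). The median was 0.83 (adjusted p = 5.93e-19; adjusted p = 0.0815 with an estimated correlation). Mesothelial markers were higher, 13 of 15 (14 adjusted over the list alone). The median was 1.49 (adjusted p = 2.43e-25; adjusted p = 0.0129 with an estimated correlation). Subcutaneous patterning genes were lower, 5 of 8 (6 adjusted over the list alone), with a median of -0.55 (adjusted p = 2.14e-09; adjusted p = 0.000774 with an estimated correlation). Schwann cell genes were lower, 4 of 10, also adjusted over the list alone. The median was -0.38 (adjusted p = 6.94e-06; adjusted p = 0.00208 with an estimated correlation). Mature adipocyte markers were lower in g with 0 of 30 called (3 adjusted over the list alone). The median was -0.17 (adjusted p = 6.3e-05; adjusted p = 0.465 with an estimated correlation). Mitosis genes were higher in g with 1 of 52 called, also adjusted over the list alone. The median was 0.13 (adjusted p = 0.013; adjusted p = 0.783 with an estimated correlation), and the call was lost without the lymphocyte-high arrays (median 0.06, adjusted p = 0.07). Glucocorticoid-induced genes were called with 3 of 13 higher (4 adjusted over the list alone). The median was 0.02 (adjusted p = 0.0299; adjusted p = 0.226 with an estimated correlation). Of 38 lists 20 passed camera, 11 higher and 9 lower in g, and 3 with an estimated correlation.

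**Figure D5:**
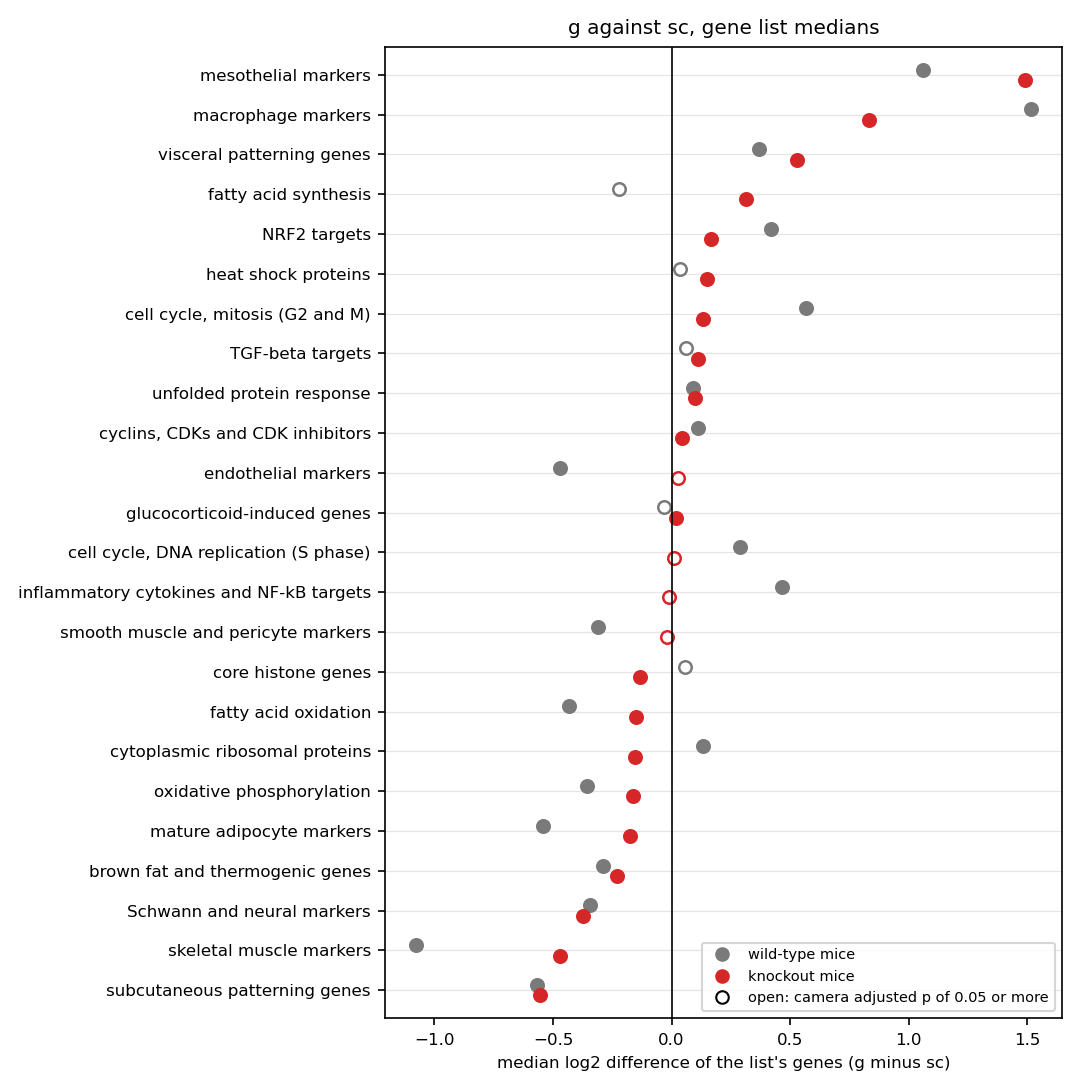
Median log2 difference (horizontal axis, g minus sc) of each gene list called in either genotype, wild-type mice in grey and knockout mice in red; open points did not pass camera at an adjusted p of 0.05. Macrophage markers lie at 1.52 in wild-type and 0.83 in knockout mice, subcutaneous patterning genes at -0.57 and -0.55.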

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

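In this part the tests of where the hepatocyte transcripts come from, the test of dilution by liver RNA and the splits of the rank correlation were chosen only after the result was seen. The hepatocyte and macrophage covariates used in other tests were chosen after the data were seen.

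For Olfm2 and the gene lists, an array stood out when its gap to the nearest of the other 4 arrays of its group exceeded 0.71 of the range of the group, which chance gives in about 1 in 20 groups. This held for 13 of 176 sets of arrays (7.39%), and for 35 of 740 among single genes named in the text (4.73%). Of the 13, 6 were on sc286WT and 3 on g309 WT. On sc286WT the lymphocyte mean was 7.80, beside 5.73 on the nearest array (gap 0.847 of the range), and the inflammatory mean was highest as well (0.711). The same array was lowest for mature adipocyte markers (10.90 beside 11.15 on the nearest array, gap 0.727) and for fatty acid synthesis (0.729), cholesterol synthesis (0.830) and olfactomedin family genes (0.761). On g309 WT senescence-associated secreted factors (0.911), inflammatory genes (0.817) and interferon-stimulated genes (0.784) were highest. The other arrays were sc307WT, highest for oxidative phosphorylation (0.856), g317 KO, lowest for TGF-beta targets (0.730), g318 KO, highest for ribosomal protein genes (0.820), and sc300KO, highest for clock genes (0.758). No explanation was tested for these arrays.

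The knockout effect on 15 genes differed between depots in a test of the difference itself. The difference, g minus sc, was 1.58 for Disp2, 1.48 for Orm3, 1.43 for Fgf9, 1.24 for Klb, 1.22 for Cadps, 1.07 for Hspb8, 1.06 for Retn and 0.81 for Mgl2. It was -0.64 for Gna13, -0.88 for Olfr1157, -1.02 for Col6a5, -1.14 for Gpr176, -1.15 for Nfasc, -1.35 for Fat3 and -1.77 for Myh15. Of these, 8 were positive and 7 negative.

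By camera 18 lists differed between depots in their knockout effect. Median differences were positive for endothelial (0.56), mesothelial (0.53), fatty acid synthesis (0.39), mature adipocyte (0.34), cholesterol synthesis (0.29), fatty acid oxidation (0.22), oxidative phosphorylation (0.20), hypoxia and glycolysis (0.14), basement membrane (0.14) and heat shock genes (0.11). They were negative for NRF2 targets (-0.16), core histone (-0.21), inflammatory (-0.24), ribosomal protein (-0.28), DNA replication (-0.29), mitosis (-0.48), macrophage (-0.61) and lymphocyte genes (-0.97). With an estimated correlation 0 of the 18 passed. Without the hepatocyte-high arrays, which leaves 1 knockout g array, the mesothelial difference was -0.35. The lymphocyte and ribosomal differences go with sc317KO and sc320KO, whose ribosomal means were 10.69 and 10.61 beside 10.01 to 10.09 on the other knockout sc arrays and whose lymphocyte means were 8.08 and 7.85. Without sc317KO or sc320KO the lymphocyte list was not called (-0.50 and -0.55), and without the 3 lymphocyte-high arrays the differences were -0.32 for lymphocyte and -0.10 for ribosomal genes.

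Among 2634 probes that carry no gene symbol here and enter none of the comparisons, 6 were called between genotypes in sc (3 higher and 3 lower, 0.228%) and 200 in g (93 higher and 107 lower, 7.59%).

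Of 100 splits of the samples into groups of the same size, the real one alone reached each count of genes with a knockout effect. Such a share lies under the 0.05 set beforehand, but 100 splits cannot show one smaller than 1 in 100. They also do not part the knockout from other differences between the genotypes, such as the hepatocyte transcripts. For sc 1 split, the real one, reached 132 genes, and the highest other gave 58. For g the real split alone (1 of 100) reached 2200, beside 292, for both depots 1 reached 1612, beside 60, and for the difference between depots 1 reached 15, beside 0. As all other splits gave 0 for that difference, any count above 0 would have met this bound. For the depots the splits of single arrays do not keep to the assumed pairs, and the real split alone reached 3468 in wild-type mice, beside 465, and 806 in knockout mice, beside 747. Among the 12 splits that part all 5 pairs of arrays, as the real one does, the highest other was 0 in wild-type and 270 in knockout mice, and 12 splits are too few for a share under 0.05. If the arrays are pairs, these splits therefore do not exclude chance for the depot counts. For the correlation of the knockout effects of the depots, 2 of 100 splits reached the real value of 0.476, the real one and another with 0.513. This is a share under the 0.05 set beforehand, for r over all arrays. Without the hepatocyte-high arrays, which leaves 1 knockout g array, r was 0.0115. By ranks chance cannot be excluded, since 10 of 100 splits reached the real rho of 0.252 and the highest other was 0.392. Whether the depots share a knockout effect across genes is therefore not settled by these splits.

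Hepatocyte transcripts were above 7 on average on 8 arrays, and Alb averaged 8.87 on wild-type and 10.9 on knockout g arrays. Each of the 16 hepatocyte genes, none of which is in another list, followed the mean of the others over the 20 arrays with r of at least 0.953, which is consistent with RNA of 1 tissue source, such as liver RNA carried into some samples. A trait of the mouse would raise both depots of a mouse together, but the means of the sc and g arrays had r = -0.265 over 10 mice (upper 95% bound 0.438, permutation p = 0.475, rho = 0.152, p = 0.683, and adjusted over 2 relations 0.475 and 0.683). Without the 2 mice farthest from the median r was 0.222. The test rests on the assumed pairs, which the arrays support little, so it does not exclude such a trait. The means per mouse also did not overlap between genotypes (4.72 to 6.85 in wild-type, 7.28 to 7.66 in knockout mice). The labels name no sort or purification that would remove such cells or RNA. List means reached 10.4 for hepatocyte (g317 KO), 8.08 for lymphocyte (sc317KO) and 9.22 for skeletal muscle markers (sc286WT). These values argue against RNA of adipocytes differentiated in culture alone on the arrays high in such markers. Whether other cells, tissue or carried-over RNA brought the transcripts, and what the remaining arrays hold, is not settled. Why the hepatocyte transcripts were higher in knockout mice, and whether loss of Olfm2 contributes, stays open and was not tested.

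In knockout g arrays macrophage and mitosis genes were lower and adipocyte markers higher. Liver RNA mixed into these arrays does not by itself account for this, since with the hepatocyte mean as a covariate the macrophage median was -0.87 with 22 of 23 genes below 0. Dilution by liver RNA alone would lower adipocyte markers, whose median was 0.36 with 1 of 30 below 0. The values are relative, so this rise does not exclude some dilution. Within groups the mitosis and macrophage means of the arrays correlated before adjustment (r = 0.653, 95% bounds 0.232 and 0.868, n = 20, permutation p = 0.0281, rho = 0.513, p = 0.0729; adjusted over 2 relations 0.0562 and 0.146), which did not pass when adjusted and rests partly on 2 arrays, without which r was 0.397. With the macrophage mean as a covariate the mitosis median was -0.18 (40 of 52 below 0, quartiles -0.40 and -0.04). This narrowly passed a bound of -0.2 for loss of macrophages as the cause. The bound was set before this value was seen, but the covariate was chosen after the data were seen. Camera still called the mitosis list with this covariate (adjusted p = 0.00284). But the macrophage means of the g arrays did not overlap (9.56 to 10.1 in wild-type, 8.27 to 9.31 in knockout). Loss of macrophages and loss of Olfm2 acting on cell division therefore cannot be told apart, a reading made after the value was seen.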

How the results depend on the processing

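Alternatives chosen only after the data were seen were those with hepatocyte, lymphocyte, skeletal muscle or macrophage means as covariates or without arrays high in hepatocyte or lymphocyte markers. The comparisons' counts and the other results of the design kept to within 1.5 times, or to their direction and side of the threshold, in 259 of their values under alternatives, moved in 50 and weakened in 2. For gene lists 1612 values stayed on their side of the threshold, 364 weakened and 4 reversed, and for named genes 4932 stayed, 746 weakened, 9 became called and 9 reversed. A list counted as reversed only where it was called in the other direction. A named gene did so where its sign changed and either fit called it. Lists that lost their call thus count as weakened even where the median changed sign. Core histone genes in g with the macrophage covariate (0.0496) are among these. Further quantile normalisation and median centring shifted the median of all genes by less than 0.1 and kept the counts of called genes within 1.5 times, as did the former for those of called lists, which were not run with median centring.

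With the hepatocyte covariate 85 genes were called in sc, 1089 in g and 2 over both depots, where the covariate does not overlap between genotypes. With the 3 covariates it was 31 in sc, 2 over both depots, 0 for the difference between depots (limma) and 1266 between depots of wild-type mice. Without the 8 hepatocyte-high arrays 43 genes were called in g, 118 between depots of knockout mice and 1 for the difference between depots, the correlation of the knockout effects was 0.0115 and Olfm2 in g was at -0.85 (adjusted p = 0.383). This exclusion also leaves fewer arrays, 1 of knockout g among them. The same exclusion reversed the mesothelial list in g (-0.30) and in the difference between depots (-0.35). Without the 3 lymphocyte-high arrays 3 genes differed in knockout effect between depots, and the ribosomal list of knockout mice reversed between depots (0.081). Serpina1b, a liver gene, was at -0.32 over both depots with the hepatocyte covariate and -0.22 with 3 covariates, not called under either. For the rest the cause was not tested.

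With the macrophage mean as a covariate, run for g alone, 4 genes and 9 lists were called and Olfm2 was at -0.82 (adjusted p = 0.454). The ribosomal list reversed (0.30, adjusted p = 2.7e-11), as did Rgs1 (0.31), H3c6 (0.033), H3c11 (0.061), Itgax (0.065), Tnf (0.40), Vcam1 (0.17) and Nr1d1 (-0.17), none of them called. The macrophage mean does not overlap between genotypes in g, so this covariate cannot be told apart from the knockout.

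The mouse as a replicate block gave 32 genes for the difference between depots, against 15, and as a fixed block 321 between depots of knockout mice, against 806, where the 10 arrays alone gave 311. Array weights gave 233 in sc and 30 for the difference between depots, trend and robust moderation 28 and the filter on dim genes 31 for that difference. That filter removes Olfm2, which has no value under it, and left 11 lists called between depots of wild-type mice. An adjusted p under 0.1 gave 264 genes in sc, 44 for the difference between depots and 1255 between depots of knockout mice. A fold of at least 1.5 gave 1047 in g, 655 over both depots, 1517 between depots of wild-type and 463 of knockout mice, as stricter and looser thresholds must. Camera with an estimated correlation called 0 lists in sc, g, both depots and the difference between depots and 4 between depots of wild-type mice; fry called 0 in sc and 2 for the difference.

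Leaving out single arrays gave 60 (without sc287WT) to 181 (without sc306KO) genes in sc, 1425 (without g307 WT) to 2305 (without g318 KO) in g, 4 (without sc307WT) to 41 (without sc286WT) for the difference between depots and 530 (without sc320KO) to 829 (without g317 KO) between depots of knockout mice. Leaving out single mice gave 1002 (that of sc309WT) to 1653 (that of sc318KO) over both depots. The alternatives differ by result: counts of lists were not run with array weights, robust moderation, all probes or only the arrays compared, and the correlation of effects was run with the dim filter, single mice left out and the hepatocyte exclusion. Only the arrays compared was not rerun for the difference between depots, which uses all arrays. Hepatocyte-high arrays could not be left out of the mean per mouse, since each knockout mouse has one, and lymphocyte-high arrays were not left out of it. The signal over background limits dim genes such as Olfm2, at 3.22 to 4.88 by group beside control medians of 4.45 to 4.84.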

Other observations

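Tests chosen only after the result was seen were the counts over the added lists, of the genes that kept their call with covariates and of the olfactory receptor genes.

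Mast cell genes fell in knockout g adipocytes, 10 of 10 (median -1.62), with the chymase Cma1 (-1.70) and the receptor Kit (-0.63) among them. The list was written after Mcpt4, Cpa3, Tpsb2 and Mrgprb1 were seen among the largest falls, so no test of it as a set is given. The list mean was 7.54 ± 0.43 in wild-type and 5.86 ± 0.32 in knockout g arrays, and 5.97 ± 0.20 and 5.64 ± 0.21 in wild-type and knockout sc arrays (SD, n = 5). In sc the median was -0.30. In g the hepatocyte covariate left 9 of 10 called (median -1.57). The macrophage covariate, which is confounded with the knockout, left 0 called, with all 10 below 0 (median -1.12). Lipid-associated macrophage genes fell in g, 7 of 9 and 8 adjusted over the list alone, with Itgax (-1.60), Ctsk (-1.56) and Gpnmb (-1.23). The median was -1.56, and 4 of 9 were called with the hepatocyte covariate (median -1.22) and 0 with the macrophage covariate (-0.36). In sc 0 were called, or 8 lower adjusted over the list alone (median -1.12), and 8 were higher in g than in sc in wild-type mice. Trem2 is in this list and in the macrophage list, and the list shares 1 gene with the secreted factors.

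Genes for the breakdown of branched-chain amino acids, which mature adipocytes use as fuel, rose in g, 16 of 18, such as Hibch (0.82), Bckdha (0.77) and Dbt (0.77). The median was 0.58. This list and that of lipid-associated macrophage genes were also written after values were seen and were not tested as sets. In sc 3 rose, Bcat2 (0.70), Ivd (0.60) and Hsd17b10 (0.44), and 8 adjusted over the list alone, with a median of 0.24. In wild-type mice 16 were lower in g than in sc (median -0.53), with Bckdha at -0.66. For hepatocyte genes, with 0 of 16 called, the median in g was 2.07.

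Apcdd1, a WNT inhibitor, rose by 1.07 in sc, 1.65 in g and 1.36 over both depots, and was called under every alternative run for these comparisons, including the covariates (1.52 and 1.48 over both depots). Cck, which encodes cholecystokinin, fell in sc (-0.90, adjusted p = 0.00791), g (-1.17, adjusted p = 0.000147) and over both depots (-1.04, adjusted p = 0.000401). It lost its call in sc with 3 covariates (-0.80, limma adjusted p = 0.186). In g it lost its call with the macrophage covariate and without the hepatocyte-high arrays (-0.64, with 1 knockout g array left).

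Some lists did not pass in knockout g adipocytes. TGF-beta targets had 3 lower, Tgfbr1 (-0.85) among them (median -0.02, adjusted p = 0.255), and interferon-stimulated genes 2 lower, Oas1a (-0.67) and Oasl2 (-0.48), but 0 adjusted over the list alone (median -0.06, adjusted p = 0.318). Endothelial markers had 1 higher, Esam (0.35; median 0.22, adjusted p = 0.0569). With the macrophage covariate, which is confounded with the knockout, the endothelial median was -0.23, with 14 of 15 below 0. Thermogenic genes had 1 lower, Ucp1 (median 0.03, adjusted p = 0.773), p53 targets 1 higher and 2 lower (median 0.10, adjusted p = 0.828), WNT targets 2 each way (median 0.06, adjusted p = 0.463) and progenitor markers 1 higher and 2 lower (median 0.00, adjusted p = 0.876). Lymphocyte markers had 0 called (median -0.41, adjusted p = 0.211). Glucocorticoid-induced genes had 2 higher and 2 lower, Tsc22d3 at 0.42 and Sgk1 at -0.64 (median 0.08, adjusted p = 0.828). Median, mean and camera differed in sign for thermogenic and skeletal muscle genes in g, for mesothelial and subcutaneous patterning genes in sc, and for lymphocyte, NRF2, glucocorticoid and smooth muscle lists over both depots, none of them called.

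The olfactory receptor genes Olfr731 to Olfr735 were lower in knockout mice over both depots, with log2 changes of -1.10, -0.96, -0.69, -1.13 and -1.27 (SE 0.17, 0.13, 0.14, 0.12 and 0.14), and lie side by side in assembly GRCm38.p6. In sc all 5 were called, and in g 3 were, while Olfr731 (-0.73, adjusted p = 0.0519) and Olfr733 (-0.27, adjusted p = 0.443) were not. A segment around Olfm2 carried with the knockout allele is excluded, since 0 of the 5 lie on the chromosome of Olfm2. A strain segment elsewhere in the genome that differs between the genotypes may lower genes that lie together, and 6 of the 40 nearest other genes were called, 15% (exact 95% bounds 5.71% and 29.8%), beside 8.26% of all genes, which leaves this open. Probes that read 1 shared transcript may also move together, and their median correlation within groups was 0.497 (0.411 to 0.651; 0.217 at the 95th percentile of random probes), just under the bound of 0.5 set for it. Gnal, a G protein subunit and not one of these receptors, correlated with their mean within groups at 0.476. It was chosen after its values were seen. A correlation with a mean of several probes is not comparable with correlations between single probes. The Gnal value therefore does not show whether other probes move together at the same level. The strain segment, the shared transcript and an effect of Olfm2 loss cannot be told apart here. Around Olfm2 itself, 0 of 40 neighbouring genes were called in sc, 6 in g (15% beside 11.3% of all genes) and 4 over both depots (10% beside 8.26%), Dnmt1, Fbxl12os, S1pr2 and Zfp846, named after their values were seen.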
